A study of Sus scrofa with 16 samples.

How the data were processed

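Gene expression was measured on 16 two-colour arrays of pig embryos collected 5 days after estrus. Per the labels, the sows received a basal diet or that diet with 0.3 mg of selenium per kg of feed, as inorganic or organic selenium, together with 10 mg of pyridoxine (vitamin B6) per kg. The basal diet held 0.2 mg of selenium and 2.3 mg of vitamin B6 per kg. Each array set embryo RNA of a supplemented sow against 1 control pool, made from 4 sows on the basal diet, with each RNA hybridised in both dye orientations. There were 4 inorganic replicates, 3 organic replicates and 1 pooled organic RNA sample, which the labels call a technical replicate. The labels name the second channel of the organic and pooled arrays with the diet in Cy5 as control, but give its dietary supplement as present; the source name was followed, so on these arrays the supplement status of the control rests on the name alone. Amplification and labelling are described in the labels' protocols; scanner, background correction and normalization are not given in the sources used here.

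The deposited values are log ratios of both channels of one array, taken here as log2. The log base and the numerator are not stated per the labels or in the table. A log10 ratio was ruled out by a largest absolute value of 9.42, and diet over control is the likely direction: on arrays with the diet in Cy5 it would result both from Cy5 over Cy3 and from sample over control. The column medians lay between -0.01 and 0.01, so the authors' values were centred. The deposited columns with opposite dyes correlated positively for the organic replicates and the pool (r = 0.69 to 0.78), and so were taken to run the same way already. The inorganic pairs correlated at only -0.0148 to 0.0015 and do not bear on the direction. Signal over background and depth are unknown for these values, and the number of arrays limits the precision.

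The 4 columns of slide 1, which hold the inorganic replicates with the diet in Cy5, were not used by probe. They correlated with the other 12 columns at -0.01 to 0.01, their own dye-swap partners included. The inorganic replicates therefore rest on 1 array each, with the diet in Cy3, and a dye effect does not cancel in their ratio to the control.

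Of 43794 probes, 18121 had 1 gene symbol, 0 had several and 25673 had none in the platform annotation. Names were updated through accessions for 104 probes and through older symbols for 241, with the Sscrofa11.1 gene table, and 4 probes kept a symbol that matched no table. Probes of one symbol were averaged and unnamed probes stood alone, which gave 37582 features. No coordinates are given, since the build behind the probes is not given in the sources used here.

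Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all features, adjusted p threshold 0.05). The design fixed before the data were examined was 1 fit of the 7 replicates, with dye-swapped arrays averaged and no dye term; features needed values in at least 2 replicates of each group. It was kept for both comparisons with the control as far as slide 1 allowed. Inorganic replicates of 1 array and organic means of 2 arrays thus shared 1 estimate of the spread, although averaging lowers array noise. Organic against inorganic selenium was moved to the diet-in-Cy3 arrays of both diets, where a dye effect cancels but slide and diet are confounded; this was settled before any count was computed. The ratio against the control leaves out the control's own spread, because the control is 1 pool.

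The order of the work bears on the counts. In all, 23 settings were run for the inorganic comparison, 22 for the organic one and 23 for organic against inorganic. Their counts, among them those of the array-level fit with a dye term, had been seen before the settings of the comparisons with the control were settled. The dye-term fit was taken for a time as the reported fit of the inorganic comparison after these counts were known. It was set back to an alternative because it was planned as one before the data were examined, and its values are printed beside the inorganic results.

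Gene lists were fixed before the data were examined and tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry. Lists with fewer than 5 measured members have counts only. Members were at first matched without their older symbols, which lost mainly oxidative phosphorylation genes; this was corrected, as the fixed lists require, after the first list results had been seen. Named genes follow a rule fixed before the data were examined. It takes, per comparison, up to 10 increases and 10 decreases of largest size among genes past the threshold with one direction in every replicate, or the 10 smallest p where fewer pass. It adds members of the selenium and vitamin B6 lists that passed in any comparison, and up to 3 passing members of each other list or its member with the smallest p. Symbols starting with LOC were not named.

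The fits were tested on simulated data with 200 changed features. For the inorganic comparison 87% of 2-fold and 98% of 4-fold changes were recovered with 7 false calls, or 89% and 96% with 133 false calls once a dye effect of the measured size (SD 0.13) was added. With a dye term, 73% of 2-fold and 96% of 4-fold changes were recovered with 11 false calls. For the organic comparison 70% and 95% were recovered, and for organic against inorganic 41% and 94%. Each simulation ran on 37562 features. Genes were drawn independently and the control pool was given no error of its own, so the false calls leave out both. The correlation of both diets was set against simulations with no diet effect, in which genes were drawn independently (20 sets) or, chosen after seeing the data, with the replicates' residual gene profiles kept whole (1000 draws for the covariance, 20 sets for calls).

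Alternatives covered probes tested alone, array medians set to 0, quantile and scale normalization, robust moderation, features with values on every array, a 1.5-fold minimum, single dye orientations, the pool as one more organic replicate, only one group in the fit, slide as a random block, a replicate block and each replicate left out. Alternatives added after seeing the data were the subtraction of the mean dye part, the pool's arrays in the dye estimate, slide 1 as deposited, both orientations for organic against inorganic with the inorganic dye part subtracted, and inorganic replicate 2 left out together with organic replicate 3. The averaging of both orientations for organic against inorganic was the fixed design; the choice to run it with slide 1 left out, as an alternative, came after the data were seen. Other analyses used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.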

Results

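Expanded blastocysts, the embryo stage with a fluid-filled cavity enclosed by trophectoderm, were compared between sows fed inorganic selenium with vitamin B6 (n = 4), organic selenium with vitamin B6 (n = 3) and a basal diet (1 pool of 4 sows). Selenium is needed for selenoproteins such as glutathione peroxidases, and vitamin B6 gives the cofactor of many amino acid enzymes. All values below are log2 ratios with diet over control as the likely direction. A value of 1 is a 2-fold difference.

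Dye-swapped arrays of the same RNA correlated across features at r = 0.68 to 0.77 for the 3 organic replicates and the pool, with mean absolute differences of 0.25 to 0.28. The rank correlations (Spearman) of these pairs were lower, at 0.33 to 0.45. Genes are not independent replicates, and no p is given for these correlations. Inorganic replicates 1, 3 and 4 correlated with each other at 0.50 to 0.73, while inorganic replicate 2 correlated with these 3 at 0.19 to 0.24. Replicates 1, 3 and 4 correlated with organic replicates 1 and 2 at 0.54 to 0.77, about as highly as with each other, and all ratios share 1 control pool. On diet-in-Cy3 arrays of both diets these values were 0.59 to 0.77. Organic replicates 1 and 2, on slide 3, correlated at 0.79. Organic replicate 3, on slide 4, correlated with them at 0.43 and 0.49 and with the pool, on the same slide, at 0.81. The pool differed from organic replicate 3 by a root mean square of 0.27, from replicates 1 and 2 by 0.47 and 0.40, and from the inorganic replicates by 0.48 to 0.55. Inorganic values are 1 diet-in-Cy3 array each and the others means of both orientations, so these differences are unlike measures. On diet-in-Cy3 arrays alone the pool correlated with organic replicates 1 to 3 at 0.447, 0.545 and 0.787. With the inorganic replicates it correlated there at 0.13 to 0.465, so it was no closer to organic replicate 1 than to inorganic replicate 1 (0.465).

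**Figure D1:**
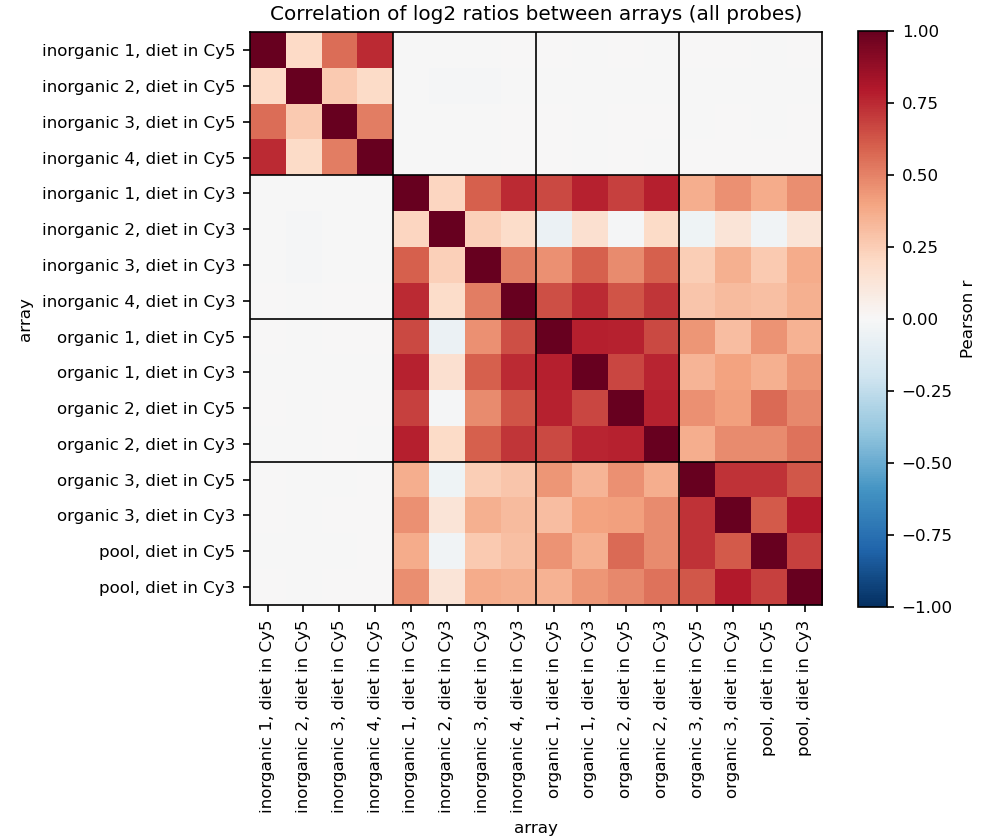
Pearson correlation of log2 ratios over all probes between the 16 arrays (both axes), with black lines between slides and colour giving r. The 4 arrays of slide 1 correlate with each other at 0.19 to 0.74 and with the other 12 at about 0, and organic replicate 3 sits with the pool.

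The question of inorganic selenium with vitamin B6 against the basal diet was addressed on the diet-in-Cy3 arrays. Among the genes with the largest increases were TLCD1 (2.05 ± 1.09, SD, n = 4), ATP5D, a subunit of the mitochondrial ATP synthase (1.95 ± 0.49), IMPDH2, an enzyme of guanine nucleotide synthesis (1.83 ± 0.85), MRPL16, a mitochondrial ribosomal protein (1.76 ± 1.00), and LTA4H, the leukotriene A4 hydrolase (1.64 ± 0.70). The largest decreases included PPP1R2, an inhibitor of a protein phosphatase (-1.76 ± 0.51), APOC2, an apolipoprotein (-1.59 ± 0.88), UGCG, the glucosylceramide synthase (-1.44 ± 0.87), ORAI1, a calcium channel (-1.43 ± 0.72), and STBD1, a glycogen-binding protein (-1.33 ± 0.21). Each of these had one direction in 4 of 4 replicates. Without a dye term limma called 2630 features at adjusted p under 0.05, 1025 higher and 1605 lower. That count uses a spread shared with organic means of 2 arrays. It was 1728 on diet-in-Cy3 arrays of both diets and 154 with only the inorganic replicates in the fit. With a dye term limma called 130, 72 higher and 58 lower, all among the 2630. Of the genes named by rule that passed, 5 kept the call with the dye term and 41 lost it. LTA4H (adjusted p = 0.036), PPP1R2 (0.029) and STBD1 (0.033) were among those that kept it, whereas TLCD1 (0.073), ATP5D (0.079) and ORAI1 (0.069) were not. The values of these 3 did not shrink with the dye term: TLCD1 was at 2.07 (SE 0.43, against 0.40 without the term), ATP5D at 2.16 (SE 0.47 against 0.38) and ORAI1 at -1.47 (SE 0.29 against 0.27), so the lost calls do not show a dye effect in these genes. Other values did shrink: over the 2630 calls the median ratio of the dye-adjusted to the unadjusted value was 0.77, and APOC2 was at -1.28 (SE 0.29 against 0.28) and UGCG at -1.24 (SE 0.32 against 0.31) with the term.

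In the group of selenium handling and selenocysteine synthesis, 2 of 12 measured members rose, 1 fell and 9 did not pass; adjusted over the list alone, 3 rose and 3 fell. INMT, a methyltransferase, rose by 0.55 ± 0.04 and had an adjusted p of 0.014, or 0.049 with a dye term. SEPHS1, a relative of selenophosphate synthetase, was at 0.55 ± 0.30 (adjusted p = 0.047, SE 0.13), or 0.50 with a dye term (adjusted p = 0.18, SE 0.17), a value about as large with a wider error. SECISBP2L, related to the protein that binds selenocysteine insertion elements, was at -0.40 ± 0.08 (adjusted p = 0.026, SE 0.07), or -0.33 with a dye term (adjusted p = 0.13, SE 0.09). The 2 probes of INMT averaged 0.80 and 0.30, and the 5 probes of SECISBP2L lay between -1.05 and -0.12. None of 15 selenoproteins passed, before or after adjustment over the list alone; SEPHS2, the selenophosphate synthetase, had the smallest p, at 0.75 ± 0.60 (adjusted p = 0.082). The selenoprotein median was 0.11, or 0.01 after subtraction of the dye part, where camera's direction was down (adjusted p = 0.43 and 0.95). Neither of 2 measured vitamin B6 salvage genes passed, with PHOSPHO2 at -0.20 ± 0.56 (adjusted p = 0.67). None of 30 enzymes that depend on pyridoxal phosphate and none of 19 one-carbon and glutathione genes passed.

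Of 23 antioxidant genes 4 rose and 19 did not pass, with 7 higher and 1 lower adjusted over the list alone. Among them were PRDX4, a peroxiredoxin (1.11 ± 0.72), TXN2, mitochondrial thioredoxin (0.82 ± 0.24), and GLRX, glutaredoxin (0.80 ± 0.25), and 0 of the 23 passed with a dye term. With that term PRDX4 was at 1.17 (SE 0.25, against 0.24 without it) and GLRX at 0.86 (SE 0.19 against 0.15), neither smaller, while TXN2 was at 0.57 (SE 0.22 against 0.18). The chaperone HSPA8 (1.41 ± 0.68) was the 1 of 22 stress genes that rose, and MCL1, which opposes apoptosis, was the 1 of 19 p53 and apoptosis genes (0.97 ± 0.50); the 3 probes of MCL1 averaged -0.20, 0.93 and 2.19. With a dye term HSPA8 was at 1.69 (SE 0.30 against 0.26, adjusted p = 0.055) and MCL1 at 0.99 (SE 0.25 against 0.22, adjusted p = 0.11). Of 47 ribosomal protein genes 11 fell and 36 did not pass, or 5 higher and 18 lower adjusted over the list alone, with RPS21 at -1.16 ± 0.52 and RPS19 at -1.07 ± 0.54. With a dye term 0 passed, and these were at -0.77 (SE 0.20 against 0.18) and -0.81 (SE 0.19 against 0.18). Of 47 oxidative phosphorylation genes 4 rose, ATP5D among them, and 4 fell, ATP5E (-0.97 ± 0.61) and ATP5G3 (-0.92 ± 0.19) among them, or 10 and 11 adjusted over the list alone. With a dye term 1 passed, and ATP5E was at -0.79 (SE 0.23 against 0.21) and ATP5G3 at -0.57 (SE 0.15 against 0.11). Of 22 DNA methylation and chromatin genes 2 rose and 1 fell. KDM6A, a histone demethylase, rose by 1.58 ± 0.38 and kept its call with a dye term (adjusted p = 0.036), and TET1, which oxidises methylated cytosine, was at 1.40 ± 0.62 (adjusted p = 0.044, SE 0.31), or 1.49 with a dye term (adjusted p = 0.097, SE 0.36), so its value did not shrink. ATP1B1, a sodium pump subunit used in forming the blastocyst cavity, was at -1.03 ± 0.23 (adjusted p = 0.011, SE 0.10) but at -0.60 with a dye term (adjusted p = 0.083, SE 0.13).

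By camera with its preset correlation, the antioxidant, p53 and apoptosis, stress, and cell cycle lists were shifted up (adjusted p = 0.040 each) and the ribosomal list down (adjusted p = 0.019). No call held with an estimated correlation (adjusted p = 0.89 each) or by fry (adjusted p = 0.13 to 0.19). With the preset correlation, all 5 calls were lost without inorganic replicate 4 (adjusted p = 0.41, 0.086, 0.55, 0.55 and 0.080 in the order above), where the cell cycle median went from 0.14 to 0.06. Without inorganic replicate 1 the 4 upward calls were lost (adjusted p = 0.052 to 0.076), without replicate 3 the antioxidant call (0.072) and without replicate 2 the p53 and apoptosis call (0.060). Leaving out replicate 2 also moved the antioxidant median from 0.37 to 0.58 and the ribosomal median from -0.19 to -0.10, and without organic replicate 3 as well, chosen after seeing the data, the ribosomal call was lost (0.11). After subtraction of the dye part, chosen after seeing the data, the ribosomal median shrank to -0.06 (adjusted p = 0.49). The p53 and apoptosis median stayed at 0.32 against 0.31, although its call was lost (adjusted p = 0.10), and the antioxidant (0.47, adjusted p = 0.0089), stress (0.39, adjusted p = 0.019) and cell cycle medians (0.21, adjusted p = 0.0089) were larger. The count of 2630 fell to 109, 143 and 149 without inorganic replicate 1, 3 or 4 and to 744 and 541 without organic replicate 1 or 2, which share in the estimate of the spread. A dye effect does not cancel in the inorganic ratios. The dye term comes from organic RNA on slides 3 and 4 and gave a wider error (median SE 0.13 against 0.10). The dye parts of the organic replicates and the pool correlated with each other at 0.31 to 0.49. In the dye-term fit 1159 features had a dye effect. Its dye coefficient (Cy5 minus Cy3) correlated across features with the unadjusted inorganic means at r = -0.32. That is the sign that a dye effect left in diet-in-Cy3 arrays would give. How much of a dye effect in the inorganic arrays the term removed was not tested.

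Organic selenium with vitamin B6 was compared with the basal diet over both dye orientations, with the control channel taken from its source name where the labels conflict. MPHOSPH8, a chromatin protein, rose by 1.82 ± 0.03 (SD, n = 3), PRDX4 by 1.78 ± 0.08, ANXA2, an annexin, by 1.74 ± 0.22, OXSM, an enzyme of mitochondrial fatty acid synthesis, by 1.64 ± 0.27, and CTTN, cortactin, by 1.46 ± 0.32. NME2, a nucleoside diphosphate kinase, was at -2.06 ± 0.63, ORAI1 at -2.01 ± 0.50, PPP1R2 at -1.78 ± 0.21, NDUFS6, a subunit of respiratory complex I, at -1.74 ± 0.04, and GCSH, of the glycine cleavage system, at -1.43 ± 0.23. Each had one direction in 3 of 3 replicates, and the 3 probes of ANXA2 averaged 0.73, 2.22 and 2.28. Limma called 230 features, 135 higher and 95 lower, with adjusted p between 0.034 and 0.048 for the genes named here.

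None of 15 selenoproteins, 12 selenium handling genes, 2 vitamin B6 salvage genes, 30 pyridoxal phosphate-dependent enzymes and 19 one-carbon and glutathione genes passed in this fit. Adjusted over the list alone, 1 handling gene was higher and 1 lower, and 1 one-carbon and glutathione gene was lower. The array-level fit with a dye term called 2 selenoproteins higher, 1 handling gene higher and 1 lower, 4 pyridoxal phosphate-dependent enzymes higher, and 1 one-carbon and glutathione gene in each direction. It counts both arrays of an RNA, linked by 1 correlation for all genes (0.42). Its false calls were not simulated for the organic comparison, so its calls here and below carry that limit. The selenoprotein median was 0.09, with 0.07 on the diet-in-Cy3 arrays and -0.035 on the diet-in-Cy5 arrays, where camera's direction was up (adjusted p = 0.31, 0.18 and 0.62). TXNRD3, a thioredoxin reductase, had the smallest p of 15 selenoproteins (1.77 ± 0.56, adjusted p = 0.15, or 0.021 in the array-level fit). SEPHS1 was at 0.59 ± 0.24 (adjusted p = 0.10, or 0.027 in the array-level fit), INMT at 0.22 ± 0.15 (0.23), SECISBP2L at -0.04 ± 0.15 (0.92) and PHOSPHO2 at 0.48 ± 0.86 (0.61). The median of the 2 vitamin B6 salvage genes, PHOSPHO2 among them, was -0.03, 0.07 and 0.70 in organic replicates 1 to 3. Of 23 antioxidant genes 2 rose, PRDX4 and GLRX (1.22 ± 0.43), and 21 did not pass, with 3 higher and 2 lower adjusted over the list alone and 4 and 2 in the array-level fit. KLF4, a pluripotency factor, was the 1 of 16 inner cell mass genes that rose (0.60 ± 0.07, adjusted p = 0.045). RPS12 (-1.72 ± 0.36) was the 1 of 47 ribosomal genes and NDUFS6 the 1 of 47 oxidative phosphorylation genes that fell. Adjusted over the list alone, 10 ribosomal genes were higher and 19 lower, and 9 oxidative phosphorylation genes were higher and 22 lower; the array-level fit called 8 and 16, and 9 and 20. None of 30 cell cycle genes passed, while 2 were higher adjusted over the list alone and 7 in the array-level fit. Camera placed oxidative phosphorylation down (median -0.31, adjusted p = 7.7e-04), cell cycle up (median 0.20, adjusted p = 7.7e-04) and ribosomal proteins down (median -0.08, adjusted p = 0.039). With an estimated correlation the adjusted p was 0.75 for each, and by fry 0.18. The ribosomal median was -0.28 on the diet-in-Cy3 arrays (adjusted p = 1.25e-04) and -0.02 on the diet-in-Cy5 arrays (adjusted p = 0.42), and -0.12 with the pool added. The ribosomal call was lost without organic replicate 3 (median -0.04, adjusted p = 0.27), without inorganic replicate 2 (0.069) or 4 (0.054) and by rank-based camera (0.27). The cell cycle median was 0.14 on the diet-in-Cy3 arrays (adjusted p = 0.0072) and 0.30 on the diet-in-Cy5 arrays (adjusted p = 0.0029), and that of oxidative phosphorylation -0.365 (adjusted p = 1.19e-04) and -0.26 (adjusted p = 0.029).

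The organic calls rest on every replicate but 2 of the inorganic group: 0 features passed in limma without inorganic replicate 3 or 4, or without organic replicate 1, 2 or 3 (5796, 5778, 3741, 3525 and 5649 at an unadjusted p under 0.05), against 602 and 1742 without inorganic replicate 1 or 2. The array-level fit with a dye term, which counts both arrays of an RNA, called 3169, and leaving out inorganic replicate 2 and organic replicate 3 together, chosen after seeing the data, gave 2036.

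**Figure D2:**
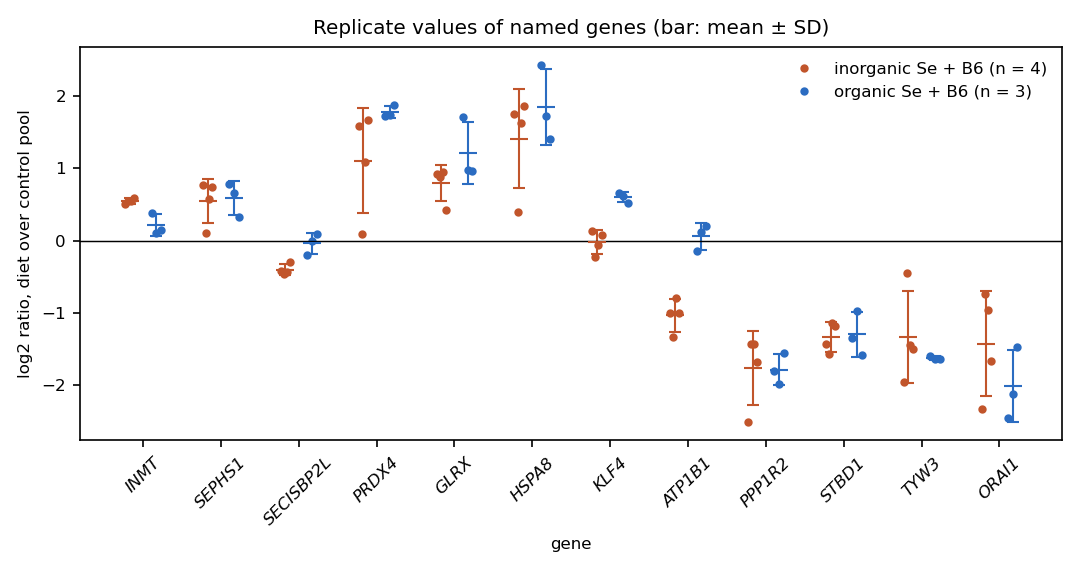
Log2 ratios over the control pool (vertical axis) of 12 named genes, one point per replicate, with bars for mean ± SD. Inorganic values come from diet-in-Cy3 arrays and organic values from both orientations, so the gap in ATP1B1 (-1.03 against 0.06) includes a dye effect; PPP1R2 and STBD1 lie below 0 in every replicate of both diets.

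The ratios of both diets were compared across genes. PPP1R2, STBD1, TYW3 (-1.34 ± 0.64 inorganic, -1.63 ± 0.02 organic), ORAI1, PRDX4 and GLRX passed in both comparisons with the control pool. Of the calls, 87 were higher in both and 81 lower in both, and 0 were opposite. Independent lists would share 3.68 and 4.06, values that leave out the shared control pool and the estimate of the spread that both comparisons share. In 20 simulations with no diet effect and genes drawn independently, no call was higher in both and at most 2 were lower in both, but these had at most 24 inorganic and 4 organic calls in all. In 20 more, chosen after seeing the data, each replicate's gene profile was kept whole. Up to 12283 inorganic calls (median 0) but 0 organic calls arose, so no overlap was possible and these sets do not bear on it. They do bear on the inorganic count: with no diet effect, the highest exceeded the 2630 reported. Across 37562 features the mean ratios correlated at r = 0.74 with a covariance of 0.109. With no diet effect and genes drawn independently, r was 0.44 to 0.47 and the covariance 0.021 to 0.024, because both diets share the control pool. With gene profiles kept whole, 95% of 1000 simulated covariances lay between -0.02 and 0.13; 41 reached the observed covariance and 256 the observed r. The control pool cannot be split, so part of the excess may come from it.

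**Figure D3:**
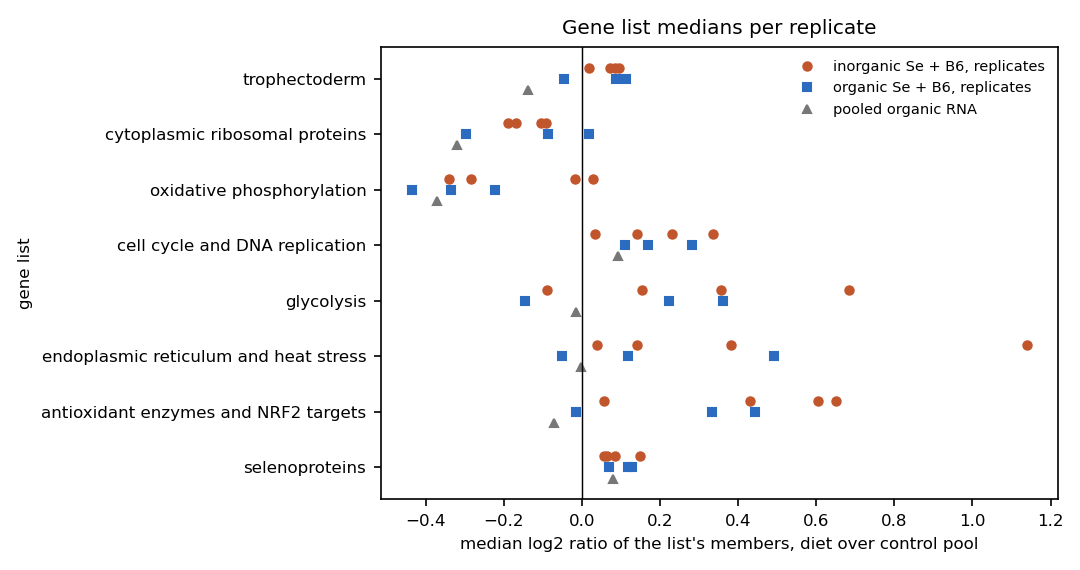
Median log2 ratio of the members of 8 gene lists (horizontal axis), one point per replicate, with the pooled organic RNA as triangles. Stress genes range from 0.04 to 1.14 between inorganic replicates, and selenoprotein medians lie between 0.06 and 0.15, with any dye effect still in the inorganic points.

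Organic and inorganic selenium were compared on the diet-in-Cy3 arrays, where the control pool and the dye cancel. Slide does not: all inorganic arrays used were on slide 2 and all organic ones on slides 3 and 4, so diet and slide cannot be told apart. No gene passed. Limma called 0 of 37544 features (smallest adjusted p = 0.96), with 1535 at an unadjusted p under 0.05, and the dye-term fit also called 0, with 1765. The fit as first designed, with slide 1 left out, so that organic replicates had both orientations and inorganic ones the diet in Cy3, called 0, with 3432. Genes with the smallest p, each with an adjusted p of 0.96, included ZNF567 (0.83 higher in organic), PGM2L1, a glucose bisphosphate synthase (1.07 higher), CD59, a complement inhibitor (1.12 higher), TNNI3, a troponin (difference -1.13), and TMEM205 (difference -0.47). For INMT the difference, organic minus inorganic, was -0.44 with a 95% interval of -0.68 to -0.20, and for GPX6, a glutathione peroxidase, 1.08 with an interval of 0.25 to 1.91. These intervals are not adjusted for the number of genes, and limma's adjusted p over all features was 0.96 for each. Adjusted over the list alone, 1 of 12 selenium handling genes was lower in organic embryos and 0 of 15 selenoproteins passed. The 2 probes of INMT averaged 0.80 and 0.30 in inorganic and 0.01 and 0.21 in organic embryos, and those of GPX6 averaged -0.99 and 0.14 in inorganic and 1.06 and 0.25 in organic embryos, so each difference rests mostly on 1 probe. PHOSPHO2 differed by 0.62 (adjusted p = 0.96), with an interval of -0.34 to 1.59.

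Oxidative phosphorylation was the list shifted by camera in this comparison, lower in organic than in inorganic embryos (median -0.32, adjusted p = 1.2e-05), although 0 of its 47 members passed alone. The adjusted p was 0.86 with an estimated correlation and 0.92 by fry. Without organic replicate 3 the median was -0.19 (adjusted p = 0.017), and without inorganic replicate 2 as well, chosen after seeing the data, it was -0.15 (adjusted p = 0.016). The list's medians per replicate were -0.34, 0.03, -0.02 and -0.28 in inorganic replicates 1 to 4, on diet-in-Cy3 arrays. Over both orientations they were -0.22, -0.33 and -0.44 in the organic replicates. The groups overlapped on these unlike measures, which are not the values tested. On diet-in-Cy3 arrays the organic median against the control was -0.365. ATP1B1 differed by 0.66, KLF4 by 0.51 and SOD2, the mitochondrial superoxide dismutase, by -0.62, with an adjusted p of 0.96 each. The median half-width of the 95% interval was 0.36, a 1.29-fold difference, and the fit recovered 41% of 2-fold and 94% of 4-fold differences in simulated data.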

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

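The tests of slide 1, of slide 4 against slide 3, the simulated mixture and the simulation with whole gene profiles were chosen after the results were seen, while the tests of the stage lists, the mixture's bound, the control pool and the splits were written before.

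In 4 genes 1 inorganic replicate lay far from the other 3, with a gap that took 0.98 of the whole range for UGCG, 0.914 for MCL1, 0.867 for GLRX and 0.839 for HSPA8. Of 81 values tested, 4 exceeded the critical value and 4.0 would by chance. Oxidative phosphorylation differed between the diets by camera (organic minus inorganic median -0.322), a call not held with an estimated correlation. The pooled organic RNA, which the reported fits did not use, had 885 features over 2-fold from the control in the same direction in both orientations, 473 higher and 412 lower, and 2 in opposite directions.

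The slide 1 columns correlated at about 0 with all others. Failed or unrelated arrays were argued against, since the pairwise correlations of the 4 columns matched those of their slide 2 partners within 0.0383. Rows in another order are a candidate explanation: probes of one gene correlated at no more than 0.0282 within these columns, against 0.10 to 0.35 elsewhere. In 6 kinds of row order tried, the largest absolute r was 0.022, so the order was not recovered. No biological explanation was tested.

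Organic replicate 3 and the pool stood apart from organic replicates 1 and 2. Replicate 3 correlated with them at 0.4873 at most, but slide and sow cannot be told apart, since no replicate was run on both slides. An earlier stage may contribute, but the oocyte list differed by 0.03 (95% interval -0.022 to 0.101) and the trophectoderm list without KRT8 and KRT18 by -0.13 (-0.456 to -0.036), which leaves it open. These intervals come from resampling the genes of each list, so they do not measure the spread between sows. In 156 features the pool lay over 1 log2 unit below the bound of an equal mixture of the 3 replicates and 1 more sow. This was under the noise count of 238, the bound chosen beforehand, but that count does not ask for low values in both arrays. A simulated equal mixture of the 3 replicates alone gave 0, but without a further sow it lies above the bound by construction. Neither count settles the makeup of the pool, which stays open.

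The ratios of both diets correlated beyond the value simulated with independent genes. The covariance was 0.1093, against at most 0.0236 from the chance spread of a pool of 4 sows, and by the bound written beforehand this spread would have been excluded. That bound was replaced after it had been passed, because it leaves out that genes vary together: with gene profiles kept whole, and array noise counted as spread between sows, 95% of 1000 draws lay between -0.0222 and 0.1301. Only 41 draws reached the observed value, inside this 2-sided range but past a 1-sided limit of 5%, so chance spread of the pool is left open. The excess of 0.0865 over the mean of the independent draws may also come from the handling or makeup of the 1 control pool or from effects that both diets share, which cannot be told apart with 1 control RNA.

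For organic against inorganic selenium, the real count past the threshold was 0, so all 35 of 35 splits of the 7 replicates must give at least as many and this count decides nothing; the highest other split gave 195. At an unadjusted p under 0.05, 17 of 35 splits, the real one included, gave as many as the real 1513, among features with all values, and the highest other gave 4742. By that count chance was not excluded. The split with 195 and 4742, singled out after the counts were seen, put inorganic replicates 2 and 3 with organic replicate 3. This may reflect a structure of the samples other than diet, and no test addressed it. On diet-in-Cy3 arrays inorganic replicate 2 correlated with organic replicate 3 at only 0.13. It correlated with every other replicate at no more than 0.24, so this low value does not decide the question.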

How the results depend on the processing

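The dye-part subtraction, the pool's arrays in the dye estimate, slide 1 as deposited, both orientations for organic against inorganic (with the dye part subtracted, or as first designed but with slide 1 left out), and leaving out inorganic replicate 2 with organic replicate 3 were chosen after seeing the data. The inorganic count of 2630 became 130 with a dye term, 442 with the dye part subtracted, 661 with the pool's arrays in the dye estimate, 1728 on diet-in-Cy3 arrays alone, 154 with only the inorganic replicates in the fit, 1274 at 1.5-fold, 12532 with slide as a random block and 4097 without inorganic replicate 2 and organic replicate 3. Leaving out 1 replicate gave 109 to 3730. The 1.5-fold minimum lowers the count by construction. In the fit with slide as a random block, all inorganic arrays lay on slide 2, so variation between slides could only widen the error of their mean. That fit does not separate slide from diet, and its rise to 12532 does not speak for more changes. For the others the cause was not tested. The organic count of 230 became 367 with probes tested alone, 725 with quantile and 705 with scale normalization, 133 with robust moderation, 3169 with a dye term at array level, 1789 with the diet in Cy5 and 1193 in Cy3, 1990 with the pool as one more replicate, 1339 with only organic replicates in the fit, 1315 with slide as a random block and 2036 without inorganic replicate 2 and organic replicate 3. Leaving out 1 replicate gave 0 to 1742. Slide was nested in diet for the organic count with slide as a random block too, so 1315 has the same limit. For the others the cause was not tested.

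For organic against inorganic limma's count was 0 in the alternatives run (1030 to 3432 at an unadjusted p under 0.05), leave-one-out included (0 to 0), except with slide 1 taken by probe as deposited, which gave 253 from columns that correlated with their dye-swap partners at about 0. With that setting ATP1B1 was at 0.005, IFIH1 at 0.019 and FOXJ1 at -0.049 against the control, the other way from the reported values. With a replicate block over replicates 1 to 3 the count was 0. Deviations of equal numbers correlated at 0.15, -0.16 and 0.01, and not every sample correlated best with its own number. These values gave no sign of a pairing by number, but deviations from means of 3 replicates cannot exclude one. The correlation of both diets stayed between 0.64 and 0.84. Among the list tests 218 outcomes kept their side of the threshold and 38 lost it. Among the named genes 2068 kept it, 548 lost it, 96 gained it and 3 turned the other way. The outcomes kept include lists and genes that did not pass in the reported fits, such as the selenoprotein list. They therefore do not give the share of calls that held. Turning every sign would leave all counts as they are and exchange higher and lower. The diet-in-Cy5 fit was not run for the inorganic group or for organic against inorganic, as it needs slide 1.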

Other observations

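Keratins were looked up after their values were seen. KRT8 and KRT18, which form the intermediate filaments of trophectoderm, were at 2.24 to 2.92 and 2.496 to 3.575 in inorganic replicates 1, 3 and 4 and at 2.73 to 3.32 and 3.01 to 3.76 in organic replicates 1 and 2. They were at 0.15 and -0.25 in inorganic replicate 2, at -2.69 and -1.29 in organic replicate 3 and at -1.07 and -0.32 in the pool. KRT19 lay between -0.43 and 0.21 in all of these samples. Of 27 measured trophectoderm genes, YAP1 was the 1 past the threshold in the inorganic comparison (-0.27 ± 0.07, SD, n = 4), with an adjusted p of 0.043 in limma, and at -0.17 (SE 0.13 against 0.06) with an adjusted p of 0.54 with a dye term.

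Markers of other cells were measured as well. Of 15 oviduct and uterine genes FOXJ1 rose in the inorganic comparison (0.33 ± 0.14), of 16 blood and immune genes S100A12 fell (-0.67 ± 0.08), and of 15 cumulus and stroma genes 0 passed; in the inorganic comparison 0 of these passed with a dye term, where FOXJ1 was at 0.18 (SE 0.09 against 0.07) and S100A12 at -0.81 (SE 0.20 against 0.13). In the organic comparison 0 of these passed, while the array-level fit called 1 blood and immune gene lower and 1 cumulus and stroma gene higher. Interferon genes had 1 lower of 20 (IFIH1, -0.36 ± 0.14), oocyte genes 1 lower of 17 (FIGLA, -0.75 ± 0.40) and sterol and fatty acid genes 1 higher of 12 (SCD, 1.37 ± 0.68) in the inorganic comparison. The 2 probes averaged 0.04 and -0.75 for IFIH1, so its value rests on 1 of them, and 2.18 and 0.56 for SCD. With a dye term IFIH1, FIGLA and SCD did not pass, at -0.24 (SE 0.09 against 0.07), -0.56 (SE 0.17 against 0.15) and 1.42 (SE 0.33 against 0.29). Of 20 blastocoel and junction genes CLDN6, a claudin, rose (0.53 ± 0.17) and ATP1B1 fell in that comparison. Neither passed with a dye term, where CLDN6 stayed at 0.49 (SE 0.14 against 0.12) while ATP1B1 shrank from -1.03 to -0.60. None of 14 imprinted, 16 primitive endoderm or 16 glycolysis genes passed in the reported fits, while the array-level fit of the organic comparison called 2 primitive endoderm genes higher and 1 lower and 3 glycolysis genes higher.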
